A study of Caenorhabditis elegans with 2 samples.

How the data were processed

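The data were ChIP-seq peak lists for ZTF-11, a zinc-finger transcription factor of the Myt1 family, from whole Caenorhabditis elegans larvae of the first larval stage, pooled over both sexes. Per the labels, the strain OP236 stably expressed ZTF-11 with a GFP-FLAG tag at its C-terminus from a transgene in an unc-119 mutant background, and chromatin was fragmented by sonication. Per the labels, 2 biological replicates with 1 technical replicate each were made. They formed 1 group, so no contrast between conditions could be tested. The replicates were compared with each other, and the lists were compared with the genome and with shuffled positions.

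Per the deposited README texts, a list of 30000 regions was made for each replicate and for the reads of both replicates together, against a control library, as input for the irreproducible discovery rate (IDR) procedure, which ranks peaks by their reproducibility. These lists hold background as well as peaks. The thresholded list, named optimal in the deposit and called the consensus here, was derived from the replicate and pooled lists, per the same texts. A peak in it need not match a region of both replicate lists. Lists on the builds ce10 and ce11 were deposited. The aligner, peak caller, IDR threshold and the strain of the control library were not given in the sources used here. The signal value of each region is the authors' own, given per list in the deposited narrowPeak files, and no scaling between lists was stated. The score in column 9 of the deposited lists is by the format a -log10 q value, but 80.0% of the pooled list's scores lay below 0, so it was treated as a score without a fixed scale. Signal was used to describe and rank regions within a list.

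The peak lists hold no read counts, so the sequencing depth of each replicate was unknown here, and no value carries a counting error from reads. Binomial intervals are exact (Clopper-Pearson, 95%) and cover counting of peaks or genes only. Peaks and neighbouring genes are not independent, so p-values over them are too small where peaks cluster.

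The ce11 lists were used with the WBcel235 genome sequence and the Ensembl release 115 annotation, which holds 19973 protein-coding genes on the nuclear chromosomes. No ce11 region extended beyond the end of its chromosome. Coordinates are ce11, counted from 1. The ce10 lists entered alternatives that need no annotation, and no coordinate was converted between builds. Positions of peaks are their deposited summits. For top lists, regions were ranked by signal and 1 summit per 200 bp was kept. Replicate regions were matched when summits lay within 200 bp. The 1000 regions of highest signal in each replicate were compared with 1000 shuffles of positions within chromosomes, with a two-sided p, of which 0.002 is the smallest possible. The shares of summits within 500 bp of a protein-coding transcript start and within 200 bp of a tRNA, snoRNA or snRNA gene were tested in the same way. The share of peaks on X was tested against the share of nuclear genome length with a two-sided exact binomial test.

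A protein-coding gene was called a target when a summit lay from 1000 bp upstream to 500 bp downstream of any of its transcript starts. Target genes were tested against 18 gene lists with a two-sided Fisher exact test over all protein-coding genes and Benjamini-Hochberg adjustment over the 18 lists. The lists were pan-neuronal genes, neuronal fate transcription factors, Notch signalling, epidermis, body wall muscle, intestine, pharynx, germline, cell cycle, glia, cilium, the loci linked to the transgene, and 6 families by name pattern (cytosolic ribosomal proteins, histones, cuticle collagens, ceh homeobox genes, hlh genes and nuclear hormone receptors). The AAGTT word, known as the motif of Myt1 family factors, was counted on both strands within 50 bp of summits and in windows of the same width centred 400 bp to either side. It was ranked among the 30 words of the same letters. Listed regions within 20 kb of ztf-11 and unc-119 were counted and set against the same count around every protein-coding gene.

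Genes were named by a rule fixed before the data were examined: the 25 consensus peaks of highest signal with the nearest protein-coding start, every list member among the consensus targets, and ztf-11 and unc-119. Other named genes were chosen after their values were seen. The main tests, the gene lists and most alternatives were also fixed before the data were examined. The share of X among the 25 highest peaks, the comparison of X with autosomal peaks, the chaperone list, the union of lists, the repeated words at small RNA peaks, the gene lists over the 1000 highest pooled regions, and several alternatives were added afterwards. The tests of the recruitment motif, repeats, GC content and transgene copies were also added afterwards, for patterns already seen in the peaks. One added alternative counted each peak once and placed peaks at random protein-coding starts. Its first run used too few placements for any single list to pass adjustment, so the number was raised to 1000, and the test is one-sided.

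Alternatives were other list lengths, overlap rules and windows, the ce10 lists, the upper 44 consensus peaks, the pooled list, summits shared by both replicates, other target rules, other motif backgrounds, and each replicate left out. With 1 replicate left out, the 88 regions of highest signal in the other replicate's own list took the place of the consensus. For replicate 1 this list was also taken with its mitochondrial regions removed.

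The steps were tested on simulated data. With 100 of 1000 peaks planted in both replicates, 10.3% were recovered as shared. With 44 of 88 summits planted at starts, the promoter share was 68.2% against 30.7% for random positions. With 4 of 59 promoter peaks planted at list members, the pan-neuronal and the Notch list were each called in 20 of 20 sets and the longer nuclear hormone receptor list in 6 of 20. Random promoter peaks gave 1 call over 20 sets. AAGTT planted in 44 of 88 windows gave an odds ratio of 4.14. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.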

Results

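ZTF-11 is a zinc-finger transcription factor known from neurogenesis. Its binding was profiled by ChIP-seq in whole first-stage larvae of Caenorhabditis elegans carrying a tagged ZTF-11 transgene. The data comprised 1 group of 2 biological replicates, and the question addressed was where in the genome the tagged protein was recovered. The deposited ce11 lists held 30000 regions per replicate and 30000 for the pooled reads, nearly all 350 bp wide, and a consensus of 88 peaks. Read depth was unknown. The 88 consensus peaks were the 88 regions of highest signal in the pooled list. Their signal ran from 40.5 to 127 with a median of 48.6, which was 3.03 times the median of 16.1 over the pooled list, and their score ran from 0.610 to 1.24. On ce10 the consensus held 71 peaks, of which 69 matched a ce11 peak on the same chromosome with a signal within 0.01. The ce11 peak at rpl-3, with a signal of 97.96, had no match under this tolerance, and the ce10 peak of the same rank, also on chromosome III, had a signal of 96.1.

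Most autosomal consensus peaks lay just upstream of protein-coding genes, among them ribosomal protein and histone genes. The peak of highest signal (127) was at chromosome III 1618968 to 1619317, an intergenic region whose summit lay 214 bp upstream of Y22D7AL.10 (WBGene00021248) and which also took hsp-60, the mitochondrial chaperonin, as a target. It ranked 3 among the nuclear regions of replicate 1 and 1 in replicate 2. The peak at chromosome III 3867442 to 3867791, 237 bp upstream of rpl-3 (WBGene00004414), a ribosomal protein gene of the large subunit, had a signal of 97.96. Summits of other peaks lay 157 bp upstream of Y17G9B.5, with rpl-20 as a second target (signal 82.4), 260 bp upstream of eif-3.C, a translation initiation factor subunit (68.4), 110 bp upstream of his-68 (64.8), 415 bp upstream of rps-28 (64.3) and 51 bp upstream of tba-2, an alpha-tubulin gene (59.02). The other autosomal peaks among the 25 of highest signal had egg-5 (87.4), ZK1248.17 (84.3), lgc-26 (67.4), Y105C5A.1 (65.4) and nhr-88 (60.1) as nearest genes, at 628 bp to 6525 bp. The lgc-26 peak ranked 8 among the nuclear regions of replicate 1 and 2308 in replicate 2, and 60% of its 31-base words occurred more than once in the genome.

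Of the 88 consensus summits, 48 lay within 500 bp of a protein-coding transcript start, or 54.5% (95% interval 43.6% to 65.2%). Shuffled positions gave 22.7% ± 4.61 (SD over 1000 shuffles, permutation p = 0.002, the smallest possible). Of these 48 summits, 45 were upstream of the start and 3 downstream. By the annotation of protein-coding genes alone, 70 summits were intergenic, 12 intronic, 4 in coding exons, 1 in a 5' UTR and 1 in a 3' UTR. Intergenic here means outside protein-coding genes, so such a summit can lie inside a small RNA gene. The target rule gave 82 genes from 59 peaks, 23 of which had more than 1 target.

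Ribosomal protein genes and histone genes were over-represented among the 82 target genes, and no neuronal list was. Of 84 cytosolic ribosomal protein genes, 7 were targets against 0.345 expected (odds ratio 24.0, Fisher exact test, adjusted p = 9.57e-07). They were rpl-3, rpl-15, rpl-20, rpl-24.2, rps-12, rps-15 and rps-28, each at a peak of its own. Without replicate 2 the nuclear regions gave 3 ribosomal protein genes (Fisher exact test, adjusted p = 0.0313), and with the mitochondrial regions kept in the list they gave 2 (adjusted p = 0.202). Without replicate 1 the count was 6. Of 50 histone genes, 4 were targets against 0.205 expected (odds ratio 22.1, Fisher exact test, adjusted p = 0.000474), namely the pairs his-67 and his-68, and his-31 and his-32, each pair at 1 peak. With each peak counted once against random placements, the permutation adjusted p was 0.0180 for ribosomal protein genes and 0.0809 for histone genes. With 1000 placements, 0.0180 is the smallest possible for a single list, so it is not a weakening of the ribosomal result. Without replicate 1 the histone count was 2 (Fisher exact test, adjusted p = 0.113). With the nearest start within 2000 bp as the target rule it was also 2 (Fisher exact test, adjusted p = 0.117). Of 50 cell cycle genes only pcn-1, which encodes the replication clamp PCNA, was a target (Fisher exact test, adjusted p = 1). A chaperone list chosen after the values were seen had 4 targets among 17 genes (cct-1, hsp-1, hsp-60 and hsp-90, Fisher exact p = 6.03e-07), which is not independent evidence.

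**Figure D1:**
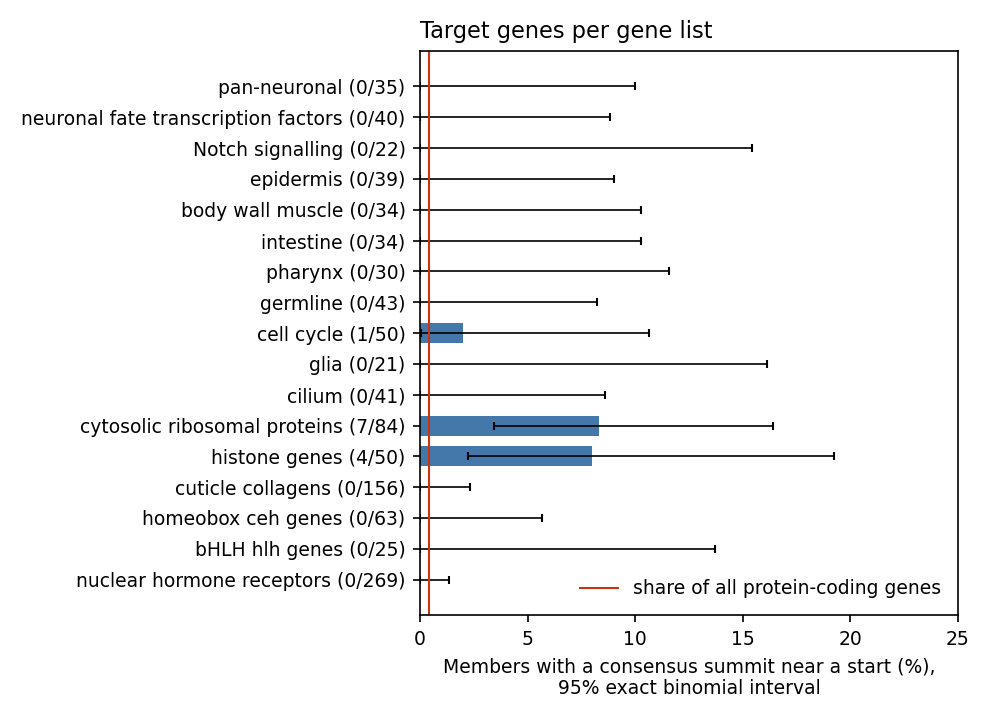
Share of the members of each gene list with more than 2 genes that were targets of the 88 consensus peaks, in percent, as bars with 95% exact binomial intervals; the red line is the share of all protein-coding genes (0.411%) and the brackets give targets over members. Ribosomal proteins (7 of 84) and histones (4 of 50) stand above the line with their whole intervals. The 4 histone genes lay at 2 peaks, so their interval counts neighbouring genes that are not independent. With each peak counted once, the permutation adjusted p for histones was 0.0809.

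None of the members of the other 15 lists was a consensus target. These included 35 pan-neuronal genes, 40 neuronal fate transcription factors, 22 Notch signalling genes, 39 epidermis, 34 body wall muscle, 34 intestine, 30 pharynx, 43 germline, 21 glia and 41 cilium genes, 156 cuticle collagens, 63 ceh and 25 hlh genes, 269 nuclear hormone receptors, and ztf-11 with unc-119. For the union of the first 10 of these lists, taken after the values were seen, 0 of 338 genes were targets (95% interval 0% to 1.09%). The expected number was 1.39, so an absence was not distinguishable from chance (Fisher exact p = 0.651). Among the 1000 highest pooled regions, the same union had 9 targets against 9.80 expected (Fisher exact p = 1). Of these 9, 5 were germline genes, against 1.25 expected for that list. Neuronal fate transcription factors had 2, epidermis 1 and cilium 1. The pan-neuronal, Notch, body wall muscle, intestine, pharynx and glia lists had 0 each. The union thus mixes unlike lists and does not speak for any single one.

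Chromosome X carried 13 of the 25 consensus peaks of highest signal, and each of these lay more than 500 bp from a protein-coding start. The nearest protein-coding starts belonged to K02D3.1, W02H3.3, Y41G9A.17, F55G7.5, F19H6.5, fbxb-58, nspc-17, gtr-1, cest-16, ftt-2, ZK899.6, F20B6.9 and F56C3.1, with signals from 61.7 to 93.3. The X peak of highest signal, at 13700690 to 13701039, was intergenic with its summit 6042 bp upstream of K02D3.1. The next, at 11094051 to 11094400, was intergenic and 3960 bp downstream of the start of W02H3.3 (signal 92.0), and that at 2996987 to 2997336 lay in an intron of Y41G9A.17 (89.7). The cest-16 peak was in an intron of mom-1, and the F19H6.5 peak in a coding exon of F19H6.6. The ftt-2 peak, 588 bp upstream of this 14-3-3 protein gene, was the closest to a start of these 13. By the wider target rule it counted as a target, as did fbxb-58 and nspc-17.

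Over all 88 consensus peaks, 20 were on X, or 22.7% (14.5% to 32.9%) against 17.7% of nuclear genome length (exact binomial p = 0.209). The share was 52% among the 25 of highest signal, a number of peaks chosen for this test after the values were seen (exact binomial p = 0.000101) and 31.8% among the upper 44 (p = 0.0268), and among the 25 highest nuclear regions of each replicate alone it was 52% for replicate 1 and 40% for replicate 2. In a comparison chosen after the values were seen, 0 of 20 X summits (0% to 16.8%) and 48 of 68 autosomal summits (70.6%, 58.3% to 81.02%) lay within 500 bp of a protein-coding start (Fisher exact p = 4.48e-09). The median distance was 2087 bp on X and 253 bp on autosomes. With the starts of all annotated genes, 68.2% of the 88 summits lay within 500 bp, a share that was not split by chromosome. Median signal was 66.9 on X and 47.4 on autosomes (permutation test, two-sided p = 4e-05). Over all 30000 pooled regions the medians were 15.997 on X and 16.06 on autosomes.

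**Figure D2:**
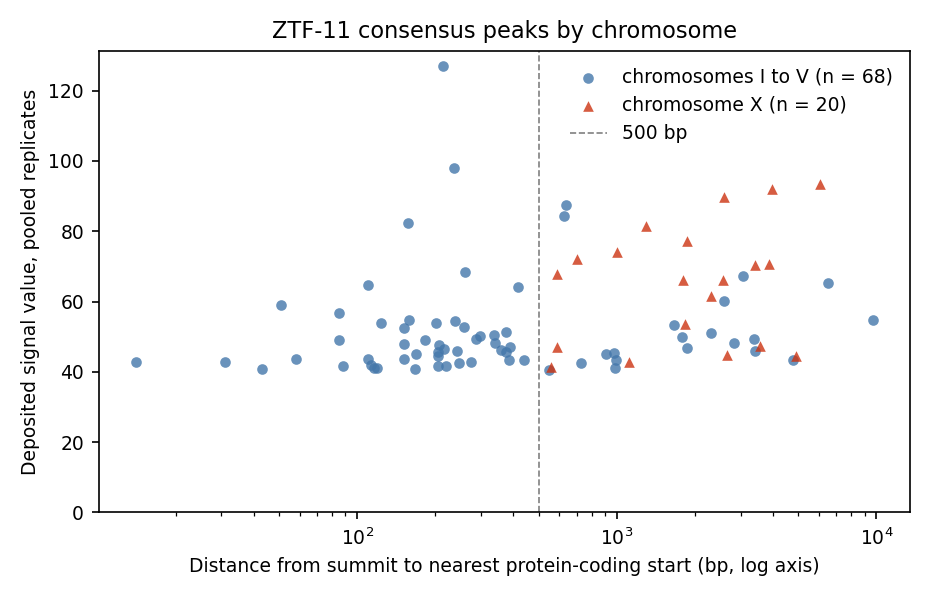
Deposited signal value of the 88 consensus peaks against the distance from summit to nearest protein-coding start in bp on a log axis, for 20 X peaks (triangles) and 68 autosomal peaks (circles), with a dashed line at 500 bp. The X peaks all lie to the right of the line, and 48 autosomal peaks lie to its left.

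Some consensus peaks lay on small RNA genes. Within 200 bp of a tRNA, snoRNA or snRNA gene lay 5 of the 88 summits, or 5.68% (1.87% to 12.8%), against 0.528% ± 0.801 (SD) in shuffles (permutation p = 0.002, the smallest possible). The peaks nearest to the protein-coding genes egg-5 (chromosome I 4172052 to 4172401) and ZK1248.17 (chromosome II 5844738 to 5845087) had their summits inside sls-2.4 and sls-2.1, genes for the SL2 spliced leader RNA. Another summit lay inside the snRNA gene sup-6 on chromosome II, a further one 73 bp from the snoRNA gene Y53F4B.47, and one on X 28 bp and 89 bp from a pair of tRNA genes. In a comparison chosen after the values were seen, all 5 of these peaks held 31-base words found more than once in the genome (4.06% to 32.8% of their words), against 3 of the other 83 consensus peaks (Fisher exact p = 1.43e-06). Repeated words are a property of the sequence at these genes, so this p-value does not bear on how the signal arose. That was not tested.

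The AAGTT word did not pass the test for enrichment at consensus summits. It occurred within 50 bp of 29 of the 88 summits (32.95%) and in 26.1% of the flanking windows, with an odds ratio of 1.39 (0.761 to 2.51, Fisher exact test, two-sided p = 0.251). By its density over the flanks it ranked 2 among the 30 words of the same letters. At the 91 summits shared by the 1000 highest regions of both replicates it was found in 24.2% of summits and 32.97% of flanks (odds ratio 0.648, 0.348 to 1.18, Fisher exact p = 0.162) and ranked 21 of 30. GC content was 41.6% at consensus summits and 36.9% in the flanks. With windows at matched distances from other starts as background, the odds ratio was 0.985.

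The replicates shared few of their highest regions, though many more than shuffled positions did. Of the 1000 regions of highest signal in replicate 1, 91 had a summit within 200 bp in replicate 2, or 9.10% (7.39% to 11.1%). Shuffles gave 0.398% ± 0.198 (SD), a ratio of 22.9 (permutation p = 0.002, the smallest possible). Of the 91 shared summits, 61 lay within 200 bp of a consensus summit. The consensus held only 88 peaks, so the share of 1000 regions does not measure agreement on the called peaks. Of the 88 consensus peaks, 85 matched a region of the replicate 1 list and 87 one of the replicate 2 list. The peaks at pqn-41, T27A8.7 and nas-5 had no match in replicate 1 and the one at npr-39 had none in replicate 2. In the 1000 highest regions, 69 were found for replicate 1, 78 for replicate 2 and 59 for both. Over the 84 peaks matched in both lists, signal in the replicates was not correlated (Spearman rho 0.00819, permutation p = 0.942, Pearson r of log2 signal 0.0452, permutation p = 0.681, adjusted p = 0.942 for both). Leaving out the 2 peaks whose replicate 1 signal lay farthest from its median gave r = 0.0384. These are correlations across peaks, which are not independent replicates, and the peaks were selected on the pooled signal. Over the 91 shared summits rho was 0.476 (permutation p = 5e-05). These were selected for high signal in both replicates. They are not all distinct sites, since at Y41G9A.17 and ZK1248.17 more than 1 of them matched the same replicate 2 region, so this p-value is too small.

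In the pooled list, the region around ztf-11 itself held more high-signal summits than the same window around any other protein-coding gene. Within 20 kb of ztf-11 (chromosome I 9904303 to 9910545) lay 10 of the 1000 highest pooled summits, against a median of 0 and a 95th percentile of 2 over protein-coding genes. Replicate 1 had 9 of its 1000 highest summits there, against a highest count of 19 around any gene, and replicate 2 had 13, the highest count in its list. The 10 pooled summits had signals from 28.1 to 51.1, and 2 of them were consensus peaks, at 9889059 to 9889408 in a coding exon of oct-1 and at 9885033 to 9885382, 981 bp upstream of nas-5. Around unc-119 (chromosome III 10902641 to 10908935), the gene mutated in this strain and the other locus linked to the transgene, the counts were 1 for the pooled list, 1 for replicate 1 and 0 for replicate 2. Of all 30000 listed regions, 21 in the pooled list, 24 in replicate 1 and 18 in replicate 2 lay within 20 kb of unc-119, against a median of 12 over protein-coding genes in each list and 95th percentiles of 21, 21 and 20.

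**Figure D3:**
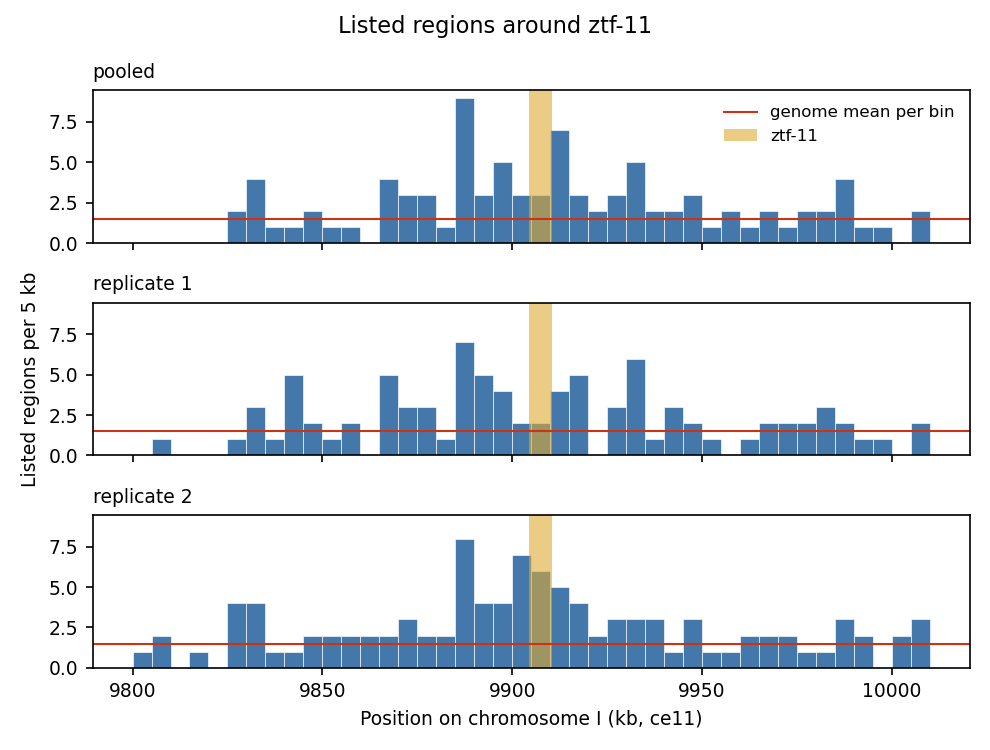
Number of listed regions per 5 kb along chromosome I around ztf-11 (shaded), in the lists of 30000 regions for the pooled reads and each replicate; the red line is the mean over the genome (1.496 regions per 5 kb). The pooled list holds 39 regions within 20 kb of the gene.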

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

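The mitochondrial regions described here were looked at only after the lists had been seen. The replicate 1 list held 23 regions on the mitochondrial chromosome, and the replicate 2 and pooled lists held 0 each. Of these 23 regions, 21 had a signal above every nuclear region of that list, with a highest signal of 1061 against 62.6 for nuclear regions. On ce10 the replicate 1 list held 24 such regions. They stood out because they lie outside the nuclear comparisons and were listed for 1 of the 2 replicates. The pooled list was made from the reads of both replicates and still held 0, so a 0 here is not a measured absence of mitochondrial signal. Whether mitochondrial regions were removed from some lists is not given in the sources used here. No explanation was tested.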

How the results depend on the processing

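Alternatives that concern nuclear regions alone, the ztf-11 region, the direction of replicate matching, the 1000 highest pooled regions, shared summits for gene lists and peaks counted once were chosen after the data were seen. Of 102 alternative values, 9 came from the pooled list at the same number of regions, which is the consensus itself and tests nothing. Of the other 93, 71 kept their direction and side of the threshold, or for counts stayed within 1.5 times. These included every alternative run for the promoter share, the small RNA share, the replicate overlap (4.60% to 10.2%) and the ztf-11 count (9 to 22). The rank correlation of signal passed the threshold over shared summits (rho 0.476) and over the whole pooled list (0.0909). The X share passed it in the upper 44 peaks (31.8%) and without replicate 1 (26.1%), and without replicate 2 it was 17.05%, below the genome share, when the mitochondrial regions stayed in, and 19.3%, above it, over nuclear regions alone. The AAGTT odds ratio fell below 1 against start-matched windows (0.985), in the upper 44 peaks (0.763) and with 1 replicate left out (0.638 to 0.837). The 2 gene lists called became 1 with the nearest start within 2000 bp and 1 with each peak counted once, and 1 to 2 without a replicate. The target genes numbered 38 for the upper 44 peaks, which follows from fewer peaks. For single gene lists, 4 values lost the call and 1 gained it. Cell cycle targets numbered 0 to 1 without a replicate. For unc-119, 2 summits among the 5000 highest regions did not exceed the median, and 0 to 1 were found without a replicate. Except for the count of targets, the cause was not tested. No paired analysis was possible because there is 1 group. Depth limits could not be given because the lists hold no read counts.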

Other observations

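The gene lists over the 1000 highest regions, the X share of all pooled regions, the share of peaks with repeated words and the start-matched AAGTT background at promoter summits were tests chosen only after the results were seen. The other tests were set out before their own results, for patterns already seen in the peaks. The share of peaks with repeated words took the place of the median share of words per peak, which was 0% at X peaks and in random X windows alike and could not decide. Among the 1000 highest pooled regions, which had 579 target genes, 16 of 84 ribosomal protein genes were targets against 2.44 expected (odds ratio 8.08, Fisher exact test, adjusted p = 3.76e-08). The 1000 highest nuclear regions of replicate 1 gave 12 (Fisher exact test, adjusted p = 2.02e-05) and those of replicate 2 gave 13 (adjusted p = 8.05e-06). Of 50 cell cycle genes, 7 were targets in the pooled list against 1.45 expected (odds ratio 5.51, Fisher exact test, adjusted p = 0.00506): the replication genes mcm-3, mcm-5, mcm-7 and pcn-1, the DREAM complex genes lin-9 and lin-54, and the kinesin gene klp-7. In the single replicates the counts were 5 for replicate 1 (Fisher exact test, adjusted p = 0.0716) and 4 for replicate 2 (adjusted p = 0.243), with lin-9 and pcn-1 in both. Germline genes had 5 targets in the pooled list (him-8, mes-3, mex-1, nos-3 and pgl-2, Fisher exact test, adjusted p = 0.0468), 2 in replicate 1 (adjusted p = 0.749) and 3 in replicate 2 (adjusted p = 0.407). Histone genes did not pass the test in these longer lists, with 4 of 50 against 1.45 expected in the pooled list (Fisher exact test, adjusted p = 0.254), 4 in replicate 1 (adjusted p = 0.214) and 5 in replicate 2 (adjusted p = 0.105).

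For the X peaks far from protein-coding starts, the motif TCGCGCAGGGAG of sites that recruit the dosage compensation complex, which binds X in hermaphrodites, was searched. With at most 2 mismatches on either strand, it lay near 13 of 20 X summits (65%, 40.8% to 84.6%), 1 of 68 autosomal summits (1.47%) and 0.65% of 2000 random X windows (Fisher exact test, X against autosomal summits, p = 8.26e-10). More copies or reads of X as a whole called for a raised X share of the 30000 pooled regions. That share was 17.2% (16.8% to 17.6%), below the 17.7% of genome length. The replicate lists did not lie below the 17.7% by more than their intervals, at 17.4% (16.96% to 17.8%) for replicate 1 and 17.8% (17.3% to 18.2%) for replicate 2, but both stayed under the 31.8% (18.6% to 47.6%) of the upper 44 consensus peaks. The lists thus gave no sign of an X-wide rise over the control library. They have a fixed length and were made against that control, so a rise shared with it would not show and stays open. Shared reads between repeats were argued against for most X peaks, since 1 of 20 (5%, 0.127% to 24.9%) held any repeated 31-base word, against 38 of 200 random X windows (19%). The 13 X peaks with the motif may be recruitment sites, but whether ZTF-11 binds there or such sites are recovered in any ChIP stays open, as no ChIP of another protein was used here. The other X peaks had no such match. Among them was the X peak of highest signal, nearest to K02D3.1, with 5 mismatches at its best position.

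The 48 consensus peaks within 500 bp of a protein-coding start were weighed against sequence properties. They include the peaks at ribosomal protein, histone and chaperone genes, for which no separate test was run. Repeats were argued against for most of these 48 promoter peaks, since 2 of them (4.17%, 0.509% to 14.3%) held any repeated 31-base word. The histone peak at his-68 was among these 2, with 1.56% of its words repeated. Median GC content at the 48 summits was 2.43 percentage points (1.14 to 3.86) above start-matched windows. That was under the 5 points set before the value was seen. The margin has no measured basis and the interval excludes no difference, so the test cannot decide on GC content. Binding through AAGTT stays open: its odds ratio was 2.28 against flanks (0.984 to 5.23, Fisher exact p = 0.0444) but 1.08 against start-matched windows (0.552 to 2.08, p = 0.875), and the flanks differ from the summits in their position relative to starts. Strong recovery of highly transcribed promoters in any ChIP was not tested and could equally give such peaks.

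The summits around ztf-11 may come from extra copies of this region in the transgene. That explanation called for a rise over the whole region, and 39 of the 30000 pooled regions lay within 20 kb of ztf-11, against a median of 12 and a 95th percentile of 21 over protein-coding genes, though the highest count around any gene was 49. Around unc-119, the count was 21, but this locus is linked to the transgene too and is not a neutral comparison. The 39 regions around ztf-11 include the 10 high-signal summits that raised the question. Their number is therefore not independent of that pattern, and binding at several places in the region could raise it too. Binding of ZTF-11 at its own locus was not tested apart from this, and the strain of the control library is not given in the sources used here.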
